A study of Mus musculus with 6 samples.

How the data were processed

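Total RNA of 6 samples of the KP1 cell line was measured on Affymetrix Mouse Gene 2.0 ST arrays, 1 array per sample. The values used are those the authors deposited, in log2 units after RMA (background correction, quantile normalization and probe set summary), per the submitters' processing notes, which name RMA without a version. The base of the logarithm is not given in the sources used here; base 2, RMA's own, was taken, and the highest value of 14.09 exceeds 11.09, the natural logarithm of a 16-bit maximum. The genome build is not given in the sources used here, so no coordinates are given. RMA pulls the arrays to a common distribution, so a change of total RNA per cell would not show, and it compresses changes of dim probe sets.

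The table held 41345 probe sets. The platform annotation pairs 23521 of them with 1 gene symbol and 1814 with several; 16010 are not listed with a gene there. A gene was represented by its brightest probe set, by the mean over the 6 arrays, among those with exactly 1 symbol, which left 22180 genes; 1082 of them had more than 1 such probe set. Older symbols in the gene lists were matched through gene identifiers and synonyms of a RefSeq gene table, and 50 listed symbols had no probe set of their own. Where a named gene had more than 1 probe set, both went the same way except for Yap1, whose values were near 0; their sizes differed (Hes5 5.11 and 0.72, Cdh1 4.03 and 1.05, Dll1 -1.63 and -0.27, St8sia5 -1.60 and -0.21, Emp1 1.85 and 0.86, Tapbp 0.68 and 0.33, Rrm2 -0.61 and -0.37, Rb1 0.04 and 0.33). No filter on dim probe sets was applied. The lowest and highest values were 0.64 and 14.09, and no array duplicated another.

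Groups were taken from the labels: 3 arrays of cells with the empty GFP vector (control) and 3 of cells with the Notch1 intracellular domain (N1ICD), both 48 hours after transfection and sorted for GFP. Differences are N1ICD minus control. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05). Each ± after a log2 change is the SE of that fit, and each ± after a group mean is the SD over 3 arrays. Notch1 also had an exact permutation test. Shifts of gene lists were tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 28 lists; camera with an estimated correlation and fry were alternatives. Counts adjusted over the list alone used the p of the same fit. Figures were drawn with matplotlib 3.10.9, and values were handled with the R package data.table, version 1.17.8.

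The design, the gene lists, the alternatives and the rule for named genes were set before the data were examined. Named were Notch1 and the 3 genes knocked out in the mouse model, the 12 largest rises and the 12 largest falls among changed genes with separated groups, up to 4 changed members of each list by size, the member with the largest change of a list without changed members, and 22 genes of Notch signaling, neuroendocrine identity and growth whatever their result. Genes named to complete a small count, and the gene families described last, were chosen after their values were seen. The lists cover Notch targets, the Notch pathway, neuroendocrine markers, neural transcription factors, REST targets and synaptic genes. They cover non-neuroendocrine small cell lung cancer markers, YAP targets, epithelial and mesenchymal genes, G1/S, G2/M and MYC genes, CDK inhibitors and p53 targets. Further lists hold interferon, antigen presentation, NF-kB, endoplasmic reticulum stress, heat shock, apoptosis and cholesterol genes. The last hold macrophage, fibroblast, endothelial, alveolar and airway, and tuft cell markers, and housekeeping genes. Some lists share members, such as Sox9, Vim, Dll3 and Lfng.

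The alternatives for the values were quantile normalization again, equal array medians, leaving out dim genes so that 16248 or 12851 genes remained, the mean over the probe sets of a gene, and testing all probe sets. The alternatives for the test were an intensity trend with robust eBayes, array quality weights, the statistic without moderation, a test against a 1.5-fold change, an adjusted p under 0.01, the replicate number as a block, and leaving out each array in turn. Cyclic loess was added after the data were examined. The fit was tested on simulated data with 22180 genes and the design of the N1ICD against control comparison. Of 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale, 13.4%, 76.1% and 97.0% were called. Of 135 calls 11 were false, and 0 genes were called by limma where nothing had changed. The simulated genes varied independently of each other and without a replicate effect, so these rates need not hold for correlated genes.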

Results

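The data are 6 Mouse Gene 2.0 ST arrays of KP1, a mouse small cell lung cancer line from a model that lacks Rb, p53 and p130. The cells were transfected with a vector expressing GFP alone (control, 3 arrays) or the intracellular domain of Notch1 together with GFP (N1ICD, 3 arrays), and GFP-positive cells were sorted after 48 hours. The labels call the 3 samples of each group biological replicates. The intracellular domain is the released, active form of the Notch1 receptor, which enters the nucleus and acts with RBPJ on target genes. The median log2 expression per array lay between 5.59 and 5.72. Correlation across genes was 0.991 to 0.994 for the 6 pairs of arrays within a group and 0.980 to 0.984 for the 9 pairs between groups. Genes are not independent replicates, so these values only describe the arrays. The number of arrays limits the precision of every value below.

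The comparison of N1ICD with control asks which genes an active Notch1 changes in neuroendocrine tumor cells. Of 23 canonical Notch target genes, 12 rose, 1 fell and 10 did not pass the test in N1ICD cells. Hes5, a repressor of neural differentiation genes, rose 34.5-fold (log2 change 5.11 ± 0.15 SE, 3 arrays per group). The repressor Hey1 rose 21.4-fold (4.42 ± 0.12), Hes1 rose by 3.46 ± 0.11 on the log2 scale, the feedback regulator Nrarp rose 8.83-fold (3.14 ± 0.11) and Heyl rose 3.78-fold (1.92 ± 0.10). Several neural and neuroendocrine regulators fell, among them Hes6 (log2 change -1.48 ± 0.14), St18 (-1.44 ± 0.22), Insm1 (-0.89 ± 0.15) and Mycl (-0.89 ± 0.12), and so did the Notch ligands Dll1 (-1.63 ± 0.19) and Dll3 (-1.43 ± 0.15). Chga, the secretory granule protein chromogranin A and a standard neuroendocrine marker, rose 1.56-fold (0.64 ± 0.12), a call lost without 4 of the 6 arrays (adjusted p up to 0.0638). At a second, dimmer probe set the change was 0.72 for Hes5 and -0.27 for Dll1, and the mean over both probe sets changed by 2.91 and -0.95.

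Notch1 itself, the transfected gene, rose from a mean log2 expression of 6.17 ± 0.19 (SD) in the control arrays to 7.76 ± 0.29 in the N1ICD arrays, a 3.01-fold difference (log2 1.59 ± 0.17 SE, limma adjusted p = 0.000889). The exact two-sided permutation p over the 20 assignments of the arrays was 0.1, the smallest that 3 against 3 arrays allow. The labels do not state the species of the insert, and the probe set may cover parts of Notch1 outside the intracellular domain, so the level of the inserted sequence itself was not measured here. Of the genes deleted in the mouse model, Rb1 (log2 change 0.04 ± 0.09, adjusted p = 0.85) and Rbl2, which encodes p130 (0.07 ± 0.12, adjusted p = 0.816), did not pass the test between groups, and Trp53 was not analysed here, because no probe set carried its symbol alone. The Rb1 and Rbl2 probe sets may lie outside the deleted parts, so their mean levels of 10.4 and 8.92 in the control arrays check nothing about the knockouts.

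**Figure D1:**
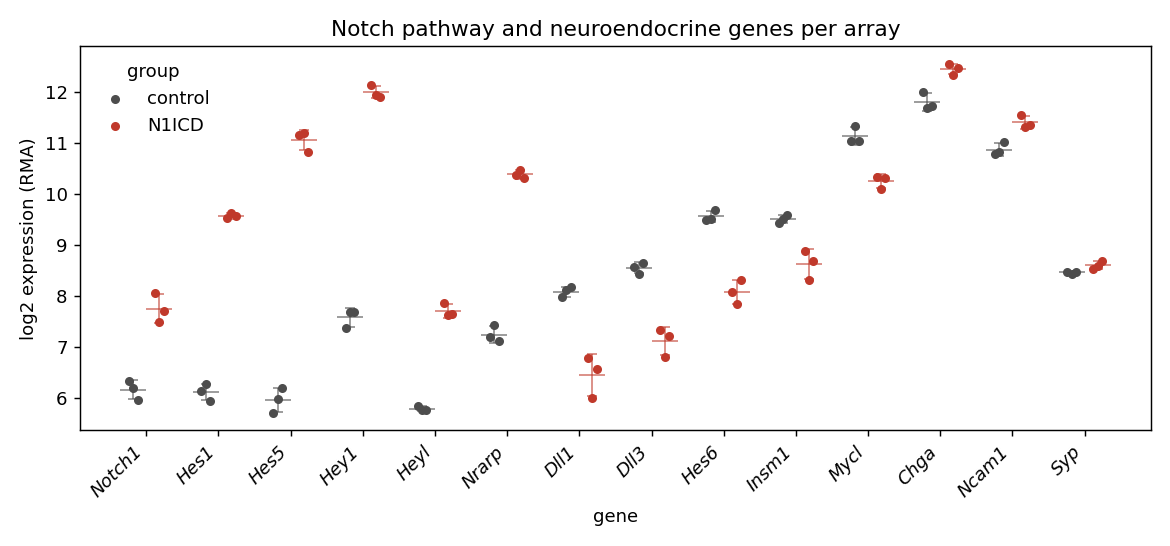
Log2 expression (vertical axis, RMA values) of 14 genes (horizontal axis) on each of the 3 control arrays (grey points) and 3 N1ICD arrays (red points); the horizontal mark is the group mean and the bar 1 SD. Hes1, Hes5, Hey1, Heyl and Nrarp are higher on all N1ICD arrays, Dll1, Dll3, Hes6, Insm1 and Mycl are lower, and Chga and Ncam1 are higher by 0.64 and 0.53.

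The 12 largest rises held 3 members of the Notch target list, Ccnd1, Tnc and Hes5, and genes outside it. Fmo2 and Fmo1, members of the flavin-containing monooxygenase family, rose by 6.26 ± 0.18 and 5.54 ± 0.10 on the log2 scale, and the G1 cyclin Ccnd1 rose 42.4-fold (5.41 ± 0.17). Depp1, the matrix protein Vtn, the Hedgehog-binding protein Hhip and the matrix protein Tnc followed with log2 changes of 5.40, 5.34, 5.18 and 5.12, and Olfml2a, Stom, Cx3cl1 and Abcc9 with 4.78, 4.74, 4.72 and 4.58. The control means of Fmo2, Fmo1, Depp1, Vtn, Hhip and Tnc (5.02 to 5.55) lay below every array median. Background was not measured, so the sizes and order of such rises hold only for the RMA values. The largest falls were smaller. The neuropeptide Y receptor Npy1r fell by 1.99 ± 0.24 on the log2 scale (3.98-fold), the enkephalin precursor Penk by 1.73 ± 0.27. The surfactant gene Sftpc fell by 1.71 ± 0.21 and the ephrin receptor Epha3 fell by 1.64 ± 0.12. Scx, St8sia5, Stap1, Atoh8, 1810008I18Rik, the serotonin receptor subunit Htr3a and the chemokine Cxcl10 also fell, with log2 changes between -1.62 and -1.56. St8sia5 had -0.21 at a second probe set and -0.90 for the mean of both. The call of Cxcl10 was lost without N1ICD replicate 2 (adjusted p = 0.0598) or N1ICD replicate 3 (adjusted p = 0.0506).

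Of 22180 genes tested, 1574 changed (7.10%), 848 higher and 726 lower in N1ICD. More genes fell than rose with dim genes left out (987 higher and 1249 lower with 12851 genes kept) or with an intensity trend and robust eBayes (1049 and 1227). In all 1574, the 3 arrays of one group lay above the 3 of the other. Of all tested genes, 26.1% were separated in this way, against 10% by chance. Changes of more than 2-fold comprised 331 rises and 97 falls, and changes of more than 8-fold 40 rises and 0 falls. Without control replicate 2, control replicate 3 or N1ICD replicate 2, 896, 887 and 823 genes changed, and 557, 579 and 548 of them rose. The number of falls was 426, 339 and 308 without control replicates 1, 2 and 3, and 473 and 275 without N1ICD replicates 1 and 2. All 1574 genes kept their direction in each of the 6 fits that left out an array, which the separation of the groups fixed in advance.

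Within the canonical Notch target list, the counts adjusted over the list alone were also 12 rises and 1 fall. Without N1ICD replicate 1, 2 fell, the second being Dtx1 (-0.37 with all arrays, adjusted p = 0.228), named after its value was seen. The list median was 0.58 (camera adjusted p = 6.81e-13; adjusted p = 0.164 with an estimated correlation). Ccnd1, Tnc, Hes5 and Hey1 rose most, Sox9 rose by 1.68 ± 0.20, and the member that fell was Lfng (-1.04, named after its value was seen), a glycosyltransferase that modifies Notch receptors. Notch3 (0.13 ± 0.13, adjusted p = 0.649) and Myc (0.10 ± 0.10, adjusted p = 0.644) did not pass the test. The control mean of Notch3, 5.52, lay below every array median. Among 37 Notch receptors, ligands and processing genes, 2 rose and 7 fell, or 4 and 9 adjusted over the list alone, and the list as a whole was not past the test (median -0.06, camera adjusted p = 0.306). The rises were Notch1 and the non-canonical ligand Dlk1 (1.14 ± 0.20), and Dll1 and Dll3 fell most.

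Neural and neuroendocrine transcription factors fell as a list: 10 of 41 measured members fell and 2 rose, 11 and 3 adjusted over the list alone (median -0.14). The camera adjusted p was 0.00402 (adjusted p = 0.312 with an estimated correlation). Hes6, St18, Insm1 and Mycl were among the falls, and the rises were the progenitor factor Sox2 (1.31 ± 0.11) and Id4, an inhibitor of bHLH factors (1.61 ± 0.20). Neurod1 had a log2 change of -0.16 ± 0.12 (adjusted p = 0.545).

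Neuroendocrine markers went both ways. Of 30 measured, 6 rose and 4 fell, 7 and 6 adjusted over the list alone, and the list was not past the test (median 0.11, mean -0.00, camera adjusted p = 0.363). The dense-core granule protein Ptprn rose by 0.86 ± 0.11, Chga by 0.64 ± 0.12 and the adhesion molecule Ncam1 by 0.53 ± 0.11. The other rises, named after their values were seen, were Resp18 (0.65), Pcsk1n (0.51) and Sez6l2 (0.49). Resp18 kept its call without any 1 array. Pcsk1n lost its call without 5 of the 6 arrays (highest adjusted p = 0.0922) and Sez6l2 without each of the 6 (highest adjusted p = 0.156). Dll3, Tph1, the enzyme of peripheral serotonin synthesis (-1.10 ± 0.16), and Gad1 (-0.67 ± 0.15) fell, as did Vgf (-0.50, named after its value was seen). The vesicle protein Syp had a log2 change of 0.14 ± 0.09 (adjusted p = 0.457). Calca was not analysed here, because no probe set carried its symbol alone. With control replicates 1, 2 and 3 and then N1ICD replicates 1, 2 and 3 left out in turn, 3, 2, 3, 2, 3 and 3 markers rose and 4, 2, 2, 2, 2 and 5 fell. The highest adjusted p without 1 array was 0.0638 for Chga and 0.0955 for Ncam1, both without control replicate 2. It was 0.115 for Gad1 without N1ICD replicate 2 and 0.0924 for Vgf without control replicate 2.

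Rest, the repressor of neuronal genes, had a log2 change of 0.30 ± 0.10 that did not pass the test (adjusted p = 0.15). All N1ICD arrays lay above all control arrays for Rest. Its control mean of 4.97 lay below every array median, where RMA compresses changes, so a larger change is not excluded. Of 45 REST target genes, 2 rose and 5 fell, 3 and 6 adjusted over the list alone (median -0.02, camera adjusted p = 0.915). Trim9, a brain ubiquitin ligase, rose by 2.44 ± 0.16, while the neuronal tubulin Tubb3 (-0.84 ± 0.13) and Fgf14 (-0.79 ± 0.13) fell. The other changed members, named after their values were seen, were Dpysl3 (0.59), Vgf (-0.50) and Cplx1 (-0.43), with Gad1. Cplx1 lost its call without each of the 6 arrays (highest adjusted p = 0.124) and Dpysl3 without control replicate 3 or N1ICD replicate 2 (highest adjusted p = 0.0576). Without control replicates 2 or 3 or N1ICD replicates 1 or 2, 2 of the REST targets fell. In this list 1 gene rose without control replicate 3 or N1ICD replicate 2. Of 39 synaptic vesicle and excitability genes, 3 rose and 3 fell, 7 and 7 adjusted over the list alone (median 0.01, camera adjusted p = 0.424). Syt5, Sv2c and Scn3b rose by 1.34 ± 0.18, 0.88 ± 0.10 and 0.87 ± 0.10, and Syt2 fell by 0.86 ± 0.11. Cacna1d (-0.62) and Kcnc1 (-0.57), named after their values were seen, fell too. The first lost its call without every array but N1ICD replicate 1 (highest adjusted p = 0.09) and the second without each of the 6 arrays (highest adjusted p = 0.13). Without control replicates 1, 2 or 3 or N1ICD replicate 2, 1 gene of the list fell.

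Markers of non-neuroendocrine small cell lung cancer rose as a list: 7 of 31 rose and 1 fell, 11 and 2 adjusted over the list alone (median 0.19). The camera adjusted p was 6.42e-05 (adjusted p = 0.254 with an estimated correlation), and the median was 0.29 without control replicate 1. The membrane-binding protein Anxa2 rose 4.76-fold (2.25 ± 0.15), Emp1 3.60-fold, the hyaluronan receptor Cd44 3.22-fold (1.69 ± 0.14) and the intermediate filament Vim 2.43-fold (1.28 ± 0.14). Yap1 (-0.01 ± 0.11, adjusted p = 0.983) and Mdk (-0.06 ± 0.14, adjusted p = 0.881) did not pass the test. The control mean of Mdk, 5.53, lay below every array median. The member that fell, Plau (-0.83, named after its value was seen), lost its call without control replicates 1 or 3 or N1ICD replicate 2 (highest adjusted p = 0.0632). Of 22 YAP and TEAD target genes, 5 rose and 3 fell, 7 and 5 adjusted over the list alone (median 0.13, camera adjusted p = 0.067). The adjusted p was 0.0415 under equal array medians, and the median was 0.082 without control replicate 3 and 0.074 with the mean over probe sets. Igfbp3, Fjx1 and Rbms3 rose by 1.91 ± 0.22, 1.69 ± 0.13 and 1.24 ± 0.13. Ccn1 rose by 0.79 ± 0.15, a call lost without control replicate 2 or N1ICD replicate 2 (adjusted p up to 0.0759). Without either of these arrays 3 of the list rose. The rest of the changed members, named after their values were seen, were Crim1 (0.46), Asap1 (-0.61), Gadd45b (-0.65) and Wwc1 (-0.70). Crim1 lost its call without every array but N1ICD replicate 1 (highest adjusted p = 0.14), Wwc1 without control replicates 1 or 3 (highest adjusted p = 0.0738) and Asap1 without N1ICD replicate 2 (adjusted p = 0.0549). Of the targets, 2 fell without control replicate 3 or N1ICD replicate 2.

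Epithelial junction genes did not move together: of 33, 3 rose and 4 fell, 3 and 5 adjusted over the list alone (median -0.01, mean 0.07, camera adjusted p = 0.872). Cdh1, the epithelial cadherin, rose by 4.03 ± 0.15 (1.05 at a second probe set, 2.54 for the mean of both) and the desmosomal protein Dsp 1.98-fold (0.99 ± 0.19), while the tight junction protein Marveld2 (-1.22 ± 0.18) and the keratin Krt7 (-0.88 ± 0.14) fell. The other changed members, named after their values were seen, were Jup (0.49), Spint2 (-0.65) and Epcam (-0.74). Their highest adjusted p with 1 array left out was 0.0743 (without control replicate 3), 0.0921 (without N1ICD replicate 2) and 0.0611 (without N1ICD replicate 3). With control replicates 1, 2 and 3 and then N1ICD replicates 1, 2 and 3 left out in turn, 2, 2, 1, 3, 2 and 2 of them rose and 4, 3, 3, 2, 2 and 3 fell. Dsp lost its call without control replicates 1 or 3 or N1ICD replicate 3 (highest adjusted p = 0.0601). Mesenchymal transition genes rose as a list, with 5 of 30 higher and 2 lower, the same counts as adjusted over the list alone (median 0.14). The camera adjusted p was 0.00432 (adjusted p = 0.416 with an estimated correlation), and the median was 0.062 without control replicate 2 and 0.21 without control replicate 1. The matrix protein Sparc rose by 4.23 ± 0.25 and the homeobox factor Prrx1 by 1.97 ± 0.22, next to Vim and, named after their values were seen, Tgfbr2 (1.27) and Snai2 (0.58). The gelatinase Mmp2 fell by 1.45 ± 0.16, and Lox (-0.73, named in the same way) lost its call without 5 of the 6 arrays (adjusted p = 0.169 without N1ICD replicate 2). Without control replicate 2, the exception, both fell. Snai2 lost its call without control replicates 2 or 3 or N1ICD replicates 1 or 2 (highest adjusted p = 0.14).

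Genes of cell division and growth were lower in N1ICD. Of 34 G1/S and DNA replication genes, 33 had a lower mean. In this list 6 fell and 0 rose, 16 and 0 adjusted over the list alone (median -0.26, camera adjusted p = 6.64e-09; adjusted p = 0.367 with an estimated correlation). Of 41 G2/M and mitosis genes, 40 had a lower mean. In this list 5 fell and 0 rose, 16 and 0 adjusted over the list alone (median -0.30, camera adjusted p = 3.66e-10; adjusted p = 0.416 with an estimated correlation). The phosphatase Cdc25b (-0.96 ± 0.14) and the spindle checkpoint kinase Bub1b (-0.75 ± 0.10) fell. Other falls were E2f8 (-0.54), Cdc6 (-0.52) and Rad51ap1 (-0.49) of the G1/S list and Kif20b (-0.52) and Cdc20 (-0.45) of the G2/M list. Each of these lost its call without 5 of the 6 arrays (highest adjusted p between 0.0793 and 0.155). The ribonucleotide reductase subunit Rrm2 fell by 0.61 ± 0.11, a call lost without control replicate 3 or N1ICD replicate 2 (highest adjusted p = 0.0578). With control replicates 1, 2 and 3 and then N1ICD replicates 1, 2 and 3 left out in turn, 1, 1, 0, 3, 0 and 3 of the G1/S genes and 2, 2, 2, 2, 2 and 5 of the G2/M genes fell. Of 28 MYC family and ribosome biogenesis genes, 9 fell and 0 rose, 19 and 0 adjusted over the list alone (median -0.33, camera adjusted p = 1.62e-08; adjusted p = 0.254 with an estimated correlation). Mycl, Srm (-0.61 ± 0.12), the rRNA processing factor Bop1 (-0.58 ± 0.10) and the nucleolar GTPase Gnl3 (-0.55 ± 0.10) were among them. In the same order of left-out arrays 4, 3, 3, 5, 2 and 7 fell, and Gnl3 lost its call without control replicate 2 or N1ICD replicate 2 (highest adjusted p = 0.0623). Srm lost its call without control replicates 1 or 3 or N1ICD replicate 2 (highest adjusted p = 0.074). The rise of Ccnd1, a cyclin of G1, ran opposite to these lists.

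CDK inhibitors and growth arrest genes showed 1 rise and 1 fall among 19, also when adjusted over the list alone (median -0.02, mean 0.03, camera adjusted p = 0.544). Gadd45g rose by 1.15 ± 0.11 and the antiproliferative gene Btg2 fell by 0.83 ± 0.13. Cdkn1a, which encodes p21, had a log2 change of -0.16 ± 0.13 (adjusted p = 0.559). Of 23 p53 target genes, 2 rose and 2 fell, 2 and 3 adjusted over the list alone (median -0.02, mean 0.13, camera adjusted p = 0.988). Perp, a desmosomal membrane protein, rose by 4.11 ± 0.16 and Eda2r fell by 1.29 ± 0.12. Ddit4 rose by 1.00 ± 0.21, a call lost without control replicates 1 or 2 or N1ICD replicates 2 or 3 (highest adjusted p = 0.0832). Aen fell by 0.39 ± 0.09, a call lost without each of the 6 arrays (adjusted p between 0.061 and 0.13). Without N1ICD replicate 1, 3 of the list rose. Of 18 apoptosis genes, 0 rose and 2 fell, 0 and 3 adjusted over the list alone (median -0.07, camera adjusted p = 0.224): the BH3-only genes Bid (-0.67 ± 0.09) and Bmf (-0.56 ± 0.09).

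Cholesterol synthesis genes rose as a list. All 17 had a higher mean in N1ICD. In this list 5 rose and 0 fell, 12 and 0 adjusted over the list alone (median 0.42, camera adjusted p = 7.58e-09; adjusted p = 0.367 with an estimated correlation). The members were Nsdhl (0.74 ± 0.14), Fdps (0.63 ± 0.12), Mvk (0.55 ± 0.10), Pmvk (0.49 ± 0.11) and, named after its value was seen, Msmo1 (0.46). With control replicates 1, 2 and 3 and then N1ICD replicates 1, 2 and 3 left out in turn, 0, 0, 3, 5, 0 and 1 of the list rose. The highest adjusted p was 0.072, 0.125 and 0.0983 for Nsdhl, Pmvk and Msmo1 without N1ICD replicate 2, and 0.0698 for both Fdps and Mvk without control replicate 2.

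Immune and stress lists did not pass the list test. Of 30 interferon and viral defence genes, 1 rose and 1 fell, also adjusted over the list alone (median -0.22, camera adjusted p = 0.203; adjusted p = 0.0036 without control replicate 2, where 0 rose and 3 fell; 2 rose without control replicate 1). Isg20 rose by 1.23 ± 0.22, a call lost without control replicate 2 or N1ICD replicates 1 or 2 (highest adjusted p = 0.0622). Cxcl10 fell by 1.56 ± 0.27, lost without N1ICD replicates 2 or 3 (highest adjusted p = 0.0598). Among 17 antigen presentation genes 1 rose, Tapbp (0.68 ± 0.10), and among 25 NF-kB and inflammatory genes 1 rose, the cytokine Csf1 (0.75 ± 0.10). None fell in either, and the counts adjusted over the list alone were the same. The camera adjusted p was 0.47 and 0.185 (0.0489 for the NF-kB list without control replicate 1, where 2 rose). Of 19 endoplasmic reticulum stress genes, 0 rose and 2 fell, also adjusted over the list alone (median -0.05, camera adjusted p = 0.306). They were Chac1 (-0.72 ± 0.18) and Asns (-0.50 ± 0.12), past the test only with all arrays or without N1ICD replicate 3 (highest adjusted p = 0.149 and 0.154, without N1ICD replicate 2). Of 19 heat shock and immediate early genes, 4 rose and 3 fell, 5 and 3 adjusted over the list alone (median 0.07, camera adjusted p = 0.238). Ier3 (1.53 ± 0.13) and Hspb8 (0.70 ± 0.10) rose and Egr1 fell by 0.86 ± 0.15. Jun (0.74 ± 0.14) and, named after their values were seen, Fos (0.69), Egr2 (-0.57) and Dusp1 (-0.44) completed the counts. The highest adjusted p with 1 array left out was 0.0694, 0.142 and 0.13 for Jun, Fos and Egr2, without N1ICD replicate 2, and 0.125 for Dusp1, without control replicate 3. In this list 2 rose without N1ICD replicates 2 or 3, and 1 fell without control replicates 1, 2 or 3 or N1ICD replicates 1 or 2.

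Markers of other cell types that a culture or sort could hold moved as follows. Of 21 alveolar type II, club and ciliated cell markers, 5 rose and 1 fell, 6 and 1 adjusted over the list alone (median 0.10). The camera adjusted p was 0.00558 (adjusted p = 0.367 with an estimated correlation, and 0.0523 without N1ICD replicate 1). The secretoglobins Scgb3a2 (3.11 ± 0.22) and Scgb1a1 (1.23 ± 0.12) and the ciliated cell gene Tppp3 (1.61 ± 0.11) rose, and Sftpc fell. Scgb3a2 and Scgb1a1 stood at mean log2 levels of 6.27 and 4.55 in the N1ICD arrays, against an array median of 5.59 to 5.72. Muc1 (0.42) and Hopx (0.38), named after their values were seen, were lost without N1ICD replicate 2 (adjusted p = 0.163 and 0.161), among other arrays. In this list 3 rose without any 1 of control replicates 1, 2 and 3 and N1ICD replicates 1 and 2. Of 14 endothelial markers, 2 rose and 1 fell, also adjusted over the list alone (median 0.08, camera adjusted p = 0.144). The receptors Kdr (3.04 ± 0.17) and Tek (1.06 ± 0.14) rose. The factor Erg fell by 1.28 ± 0.24, a call lost without control replicates 1 or 3 (highest adjusted p = 0.0584). Of 16 fibroblast markers, 1 rose and 1 fell, 2 and 2 adjusted over the list alone (median 0.13, camera adjusted p = 0.224). Pdgfrb (0.89 ± 0.14) rose, and Pdgfra (-0.74 ± 0.14) fell except without control replicates 2 or 3 or N1ICD replicates 1 or 2 (highest adjusted p = 0.0736). Of 18 macrophage and leukocyte markers, 1 rose and 0 fell, also adjusted over the list alone (median -0.01, mean 0.04, camera adjusted p = 0.47). It was Lyz2 (0.52 ± 0.12), whose call was lost without each of the 6 arrays (adjusted p between 0.0519 and 0.11). Of 12 tuft cell markers, 2 rose and 0 fell, also adjusted over the list alone (median 0.03, camera adjusted p = 0.0522). They were Sox9 and the kinase Dclk1 (1.29 ± 0.13). The adjusted p was 0.0152 without control replicate 1 and 0.0106 without N1ICD replicate 3, where 3 rose. It was 0.0405 under equal array medians, 0.0347 with the mean over probe sets and 0.036 with 12851 genes kept. Of 16 housekeeping genes, 0 rose and 0 fell by limma, also adjusted over the list alone (median 0.04, camera adjusted p = 0.398); the largest change was Pgk1 (0.44 ± 0.22, adjusted p = 0.334).

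**Figure D2:**
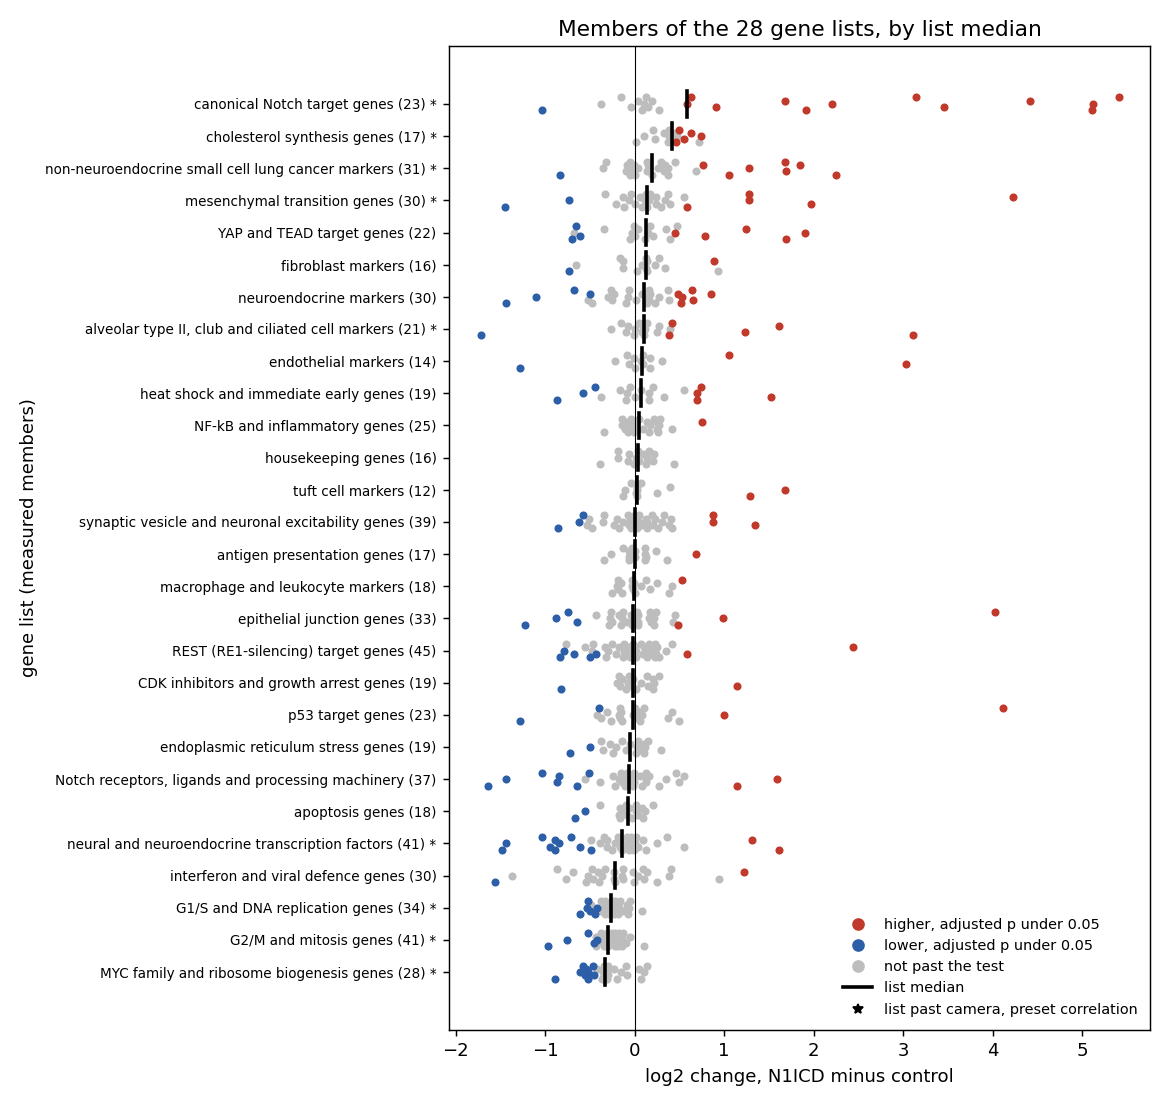
Log2 change, N1ICD minus control (horizontal axis), of each measured member of the 28 gene lists (rows, with the number of measured members), sorted by list median (black bar); red points rose, blue points fell and grey points did not pass the test, and a star marks the 9 lists past camera with the preset correlation. The Notch target list has the highest median, 0.58, and the MYC family and ribosome biogenesis list the lowest, -0.33.

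By camera with the preset correlation, 9 of the 28 lists shifted, 5 up and 4 down. With an estimated correlation between genes 0 lists passed, with a smallest adjusted p of 0.164, and 4 had an unadjusted p under 0.05. The test fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, called 12. These included the YAP targets (adjusted p = 0.0137), apoptosis genes (0.0267) and endothelial markers (0.0321), which camera did not call. With 1 array left out the medians of lists not past camera moved by over 1.5 times, in some cases across 0. They were 0.06 to 0.15 for neuroendocrine markers, -0.09 to 0.01 for the Notch pathway, -0.04 to 0.00 for REST targets, -0.01 to 0.03 for synaptic and -0.04 to 0.04 for epithelial genes. CDK inhibitors had -0.05 to 0.05, p53 targets -0.13 to 0.03, apoptosis genes -0.09 to -0.04, interferon genes -0.33 to -0.08, antigen presentation genes -0.05 to 0.04 and NF-kB genes 0.00 to 0.11. Endoplasmic reticulum stress genes had -0.14 to 0.07, heat shock genes 0.01 to 0.12, macrophage markers -0.11 to 0.06, fibroblast markers 0.01 to 0.21, endothelial markers 0.01 to 0.12, tuft cell markers 0.00 to 0.11 and housekeeping genes 0.02 to 0.12. With 12851 genes kept the median was 0.91 for the Notch targets and -0.25 for the neural factors. The median and the mean of a list differed in sign for the neuroendocrine markers, where camera followed the median, for the epithelial junction, CDK inhibitor and macrophage lists, where camera followed the mean, and for the p53 targets, where it followed the median.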

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

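The tests of the balance between rises and falls were chosen only after that result was seen, and cyclic loess was added after the data were examined; the other tests were set before their results were seen.

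Among the 16010 probe sets not listed with a gene, which no comparison of genes uses, 24 were higher and 27 lower in N1ICD in the fit of all probe sets, with a largest rise of 2.87. Among the 1814 probe sets with several gene symbols, 26 were higher and 2 lower, with a largest rise of 1.98. These are signals in data outside the gene comparison. In the same fit 498 of the 23521 probe sets with 1 symbol were higher and 228 lower, a larger share than among the probe sets not listed with a gene.

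Rises were larger than falls: of the changes past 2-fold, 331 were rises and 97 falls. After cyclic loess 80.0% were rises (339 of 424, exact 95% interval 75.8 to 83.7), which argues against an intensity-dependent shift between the groups as the whole cause. A measurement floor that hides falls of dim genes stays open. Among the brightest 5545 genes by the mean of all arrays 71.8% were rises (94 of 131, exact interval 63.2 to 79.3), but among the brightest genes by the control mean, taken in the same share, 41.6% were (42 of 101, 31.9 to 51.8), with a largest rise of 2.12 and a largest fall of -1.99. In the other 3 sets of 5545 genes by control mean, from dim to bright, rises and falls past 2-fold numbered 29 and 0, 120 and 2, and 140 and 36; background was not measured, and activation of dim genes by N1ICD cannot be told apart from the floor with these values.

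The G1/S, G2/M and MYC lists were lower in N1ICD. An intensity-dependent shift of bright genes as the whole cause is argued against: among 10000 random lists matched on level, the percentile of the list median was 0 for each of the 3 lists. Variation between arrays shared by coregulated genes would let the groups overlap in at least 1 list, but they did so in 0 of the 3: the mean log2 per array was 9.42 to 9.54 in N1ICD and 9.71 to 9.76 in control for G1/S, 9.57 to 9.77 and 9.91 to 9.99 for G2/M, and 9.23 to 9.34 and 9.57 to 9.61 for MYC. It stays open because 3 arrays separate from 3 by chance in 10% of splits and camera with an estimated correlation called none of the lists. The sizes of their medians were 0.26, 0.30 and 0.33 in the real grouping and at most 0.15, 0.19 and 0.17 in the other splits of the arrays. Those splits mix control and N1ICD arrays, so any difference between the groups makes their medians smaller, and they say little about chance. An effect of N1ICD on proliferation remains a hypothesis.

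Neural transcription factors had a lower median than neuroendocrine markers (-0.14 and 0.11, difference -0.25). The two-sided permutation p was 0.00601 over 100000 shuffles of membership, a test that treats genes as independent. This p is not corrected for the choice of this pair among all the lists, so chance membership of the lists stays open. An intensity-dependent shift is argued against, since 100.4% of the difference was left after cyclic loess. Among changed genes, 10 factors fell and 2 rose against 4 and 6 of the markers (two-sided Fisher's exact p = 0.0743). Both groups of genes held changes, such as Ptprn (0.86), Tph1 (-1.10) and Dll3 (-1.43) among the markers, and an effect of N1ICD that differs between factors and markers remains a hypothesis.

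The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1574 changed genes and the highest other split 0, so that 1 split, the real one, reached that count. Every other split mixes control and N1ICD arrays, so a difference between the groups widens the spread within its sets and lowers its count. The 0 therefore says little about chance. For shifted lists the real split gave 9 and the highest other split 12, so that 2 splits reached the real count. Among the shifted lists, the size of the mesenchymal median was 0.139 in the real split and 0.141 in another, and 5 of the 10 splits, the real one included, gave an alveolar and airway median as large as the real 0.104 (highest 0.143).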

How the results depend on the processing

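Cyclic loess was chosen only after the data were examined; all other alternatives were set before. Of 2723 values under the alternatives, 2382 stayed on the same side of the threshold or, for counts, within 1.5 times the main count. Of the rest, 305 were no longer past the threshold, 11 became so, 25 counts moved and 0 reversed. A change of sign was counted as a reversal only if the value passed the threshold in the main fit or under the alternative. Values that passed in neither could change sign, as Yap1 did (-0.08 to 0.09). Of 106 named genes that passed, 79 passed in each of the 6 fits without 1 array and 27 did not in at least 1. The statistic without moderation ended the call of 55 of them, a test against 1.5-fold 54, an adjusted p under 0.01 30 and testing all probe sets 29. All 1574 changed genes, where measured, kept their direction under every setting. Where a setting kept the values and changed only the test or left out an array, the separation of the groups fixed this in advance.

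Counts of changed genes lay between 1391 and 1559 under quantile normalization, equal medians and the mean of probe sets, and cyclic loess gave 1546 (920 higher, 626 lower). Testing all probe sets gave 805 (548 higher, 257 lower), the statistic without moderation 598 (402, 196), a test against 1.5-fold 282 (255, 27) and an adjusted p under 0.01 668 (460, 208). Falls outnumbered rises with 16248 genes kept (1012 higher, 1080 lower) and with 12851 (987, 1249), where fewer genes were tested, and with a trend and robust eBayes (1049, 1227), where the cause was not tested. Without 1 array, where fewer samples were used, 823 to 1230 genes changed, 548 to 709 higher and 275 to 585 lower. Notch1 (1.59) had an adjusted p of 0.051 without moderation.

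With an estimated correlation 0 lists passed in place of 9: the medians stayed at 0.58 (Notch targets), -0.14 (neural factors), 0.19 (non-neuroendocrine), 0.14 (mesenchymal), -0.26 (G1/S), -0.30 (G2/M), -0.33 (MYC), 0.42 (cholesterol) and 0.10 (alveolar and airway), while the test allowed for correlated genes. The alveolar and airway list was not past the test with dim genes left out (median 0.098 with 16248 and 0.25 with 12851 genes kept), where the cause was not tested; without 1 array its median was 0.020 to 0.16.

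The replicate numbers are shared between the groups, and the deviations of same-numbered arrays correlated at 0.23, 0.01 and 0.20. Control replicate 1 with N1ICD replicate 3 gave -0.23, and control replicate 3 with N1ICD replicate 1 gave -0.20. Deviations within a group offset each other, so these values are not independent. They go with a replicate effect shared between the groups that sets number 1 against number 3. Under such an effect, arrays of number 2 that lay between the others would show little correlation. The 0.01 of number 2 therefore cannot decide whether it shares the effect. The main fit, set before the data were examined, held no block, so such an effect stays open there. With a replicate block 1518 genes changed (814 higher, 704 lower), 1330 of them shared with the fit without it. Control replicate 2 correlated best with N1ICD replicate 3 (0.06), not with its own number. Signal near the background limits dim genes, whose changes RMA compresses.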

Other observations

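The gene families below were put together only after the changes of some of their members were seen, and their tests were chosen then; the test of the held-out glial list was set before its result was seen.

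Several families of receptors and enzymes that no list covers as a whole held changes in N1ICD cells. Of 7 genes of the gp130 cytokine receptor family and its signaling, Osmr rose by 4.04 and Lifr by 3.65, both also without any 1 array, while Il6st (0.55), Stat3 (0.62) and Il6ra (-0.53) passed with all arrays and lost their calls without 5 of the 6 (highest adjusted p = 0.113, 0.084 and 0.124). Cntfr (0.44) and Socs3 (-0.13) did not pass the test. In the flavin-containing monooxygenase family Fmo1, Fmo2 and Fmo4 (1.36) rose and Fmo5 did not pass the test (0.15). The soluble guanylate cyclase subunits Gucy1a1 (3.35) and Gucy1b1 (1.75) rose with the neuronal nitric oxide synthase Nos1 (3.12), whose product activates that enzyme, while Gucy1a2 (-0.32), Nos2 (0.02) and Nos3 (-0.03) did not pass the test. Among 13 vascular growth factors and receptors, Pgf (3.08), Kdr (3.04), Vegfc (1.96) and Tek (1.06) rose, of which Kdr and Tek are also in the list of endothelial markers. Vegfd (0.96) and Nrp1 (-0.78) lost their calls without N1ICD replicate 2 (adjusted p = 0.0658) and control replicate 3 (adjusted p = 0.087), among other arrays; the fixed list of endothelial markers was not past the test (camera adjusted p = 0.144).

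Neuropeptides and their receptors split: of 20, 5 rose and 5 fell, the same counts in each fit without 1 array and under the 3 scalings. Neurotensin (Nts) rose by 2.73, and the receptors Adcyap1r1, Tacr1, Avpr1a and Sctr by 2.52, 2.25, 2.24 and 1.90. Npy1r, Penk, the islet amyloid peptide Iapp (-1.20), Sstr2 (-1.09) and Glp1r (-1.03) fell. Receptors for other transmitters that fell were Htr3a, the cannabinoid receptor Cnr1 (-1.52) and the histamine receptor Hrh3 (-1.09). Among D-type cyclins Ccnd1 rose by 5.41, Ccnd2 fell by 1.35, a call lost without N1ICD replicate 2 (adjusted p = 0.0686), and Ccnd3 did not pass the test (0.01). Among 13 Hedgehog pathway genes Hhip rose by 5.18 and Gli3 fell by 1.48, while Gli1 (-0.09) and Ptch1 (0.17) did not pass the test.

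A hypothesis was that genes of astrocytes and radial glia rise as a set, since 15 such genes, among them Tnc, Sparc, Megf10 (3.76), Aldoc (3.75) and Cspg5 (2.57), had been seen among the large rises. A held-out list of such genes, none of them among those 15, was then tested. Of 29 measured, 6 rose and 0 fell: Fgfr3 (1.57), Bcan (1.30), Clu (1.11), Timp4 (1.00), Slc1a2 (0.71) and Nes (0.65). The camera p was 0.000427 (p = 0.0338 with an estimated correlation), both without adjustment. The 28 fixed lists were judged on adjusted p, and 0 passed with an estimated correlation. The median of the held-out list, 0.13, lay at the percentile 99.9 of level-matched random lists, a measure that treats genes as independent. The arrays were those in which the 15 genes had been seen, so genes regulated together give no separate support. A partial glial program remains a hypothesis. Gfap (0.05), Aqp4 (-0.03), Slc1a3 (0.24), Gja1 (0.12) and Fabp7 (-0.27) did not pass the test. Slc1a2 lost its call without control replicate 2 (adjusted p = 0.0719) and Nes without 4 arrays (adjusted p = 0.125 without control replicate 3). The median was 0.083 without control replicate 3 and 0.087 without N1ICD replicate 2. Without control replicate 2, 4 of the list rose, and without N1ICD replicate 1, 1 fell. The same list also holds genes that other cell types express, such as Clu and Nes, and a glial identity of the cells was not measured.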
